A study of Mus musculus with 5 samples.

How the data were processed

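The study measured RNA in single cells from the cerebral cortex of male mice. In 4 of the 5 libraries the mice had gone through occlusion of the middle cerebral artery for 60 minutes, which blocks and then restores blood flow to a large part of one hemisphere, and tissue bordering the infarct was taken 4 days later, per the labels' protocols. The fifth library was labelled as sham surgery in the control genotype, and its label gives no day after surgery. Controls carried the Padi4 gene with both copies flanked by loxP sites. In the conditional knockout (cKO), Cre recombinase driven from the Slc17a7 and Slc32a1 loci was meant to delete that flanked part in excitatory and inhibitory neurons. The groups were sham control (1 library), day 4 control (2 libraries) and day 4 cKO (2 libraries). The labels do not say how many animals a library held or whether libraries of a group came from separate animals, so p-values measure the spread between these libraries, and the lone sham library was assumed to vary like the others.

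Tissue was digested with pronase for 75 minutes and sorted by flow cytometry, per the labels' protocols. Cells positive for Thy1, a neuronal surface protein, were kept, and cells carrying ACSA2 (astrocytes), CD31 (endothelium), CD45 (leukocytes), O4 (oligodendrocyte lineage), CD140a (oligodendrocyte precursors and fibroblasts) or CD140b (mural cells) were excluded. Libraries were made with a droplet kit that tags the 3' end of each transcript with a unique molecular identifier (UMI), per the labels' protocols. Reads were processed with Cell Ranger 6.0.1 against mm10, per the submitters' processing notes, and the matrix headers name Cell Ranger 4. The deposited matrices hold raw UMI counts, not normalised, for 32285 genes and every barcode seen (907955 to 2525612 per library), so cell calling was left to the user. Whether counting used the strand is not given in the sources used here. Of the 32285 gene identifiers, 32235 (99.8%) matched the GENCODE mouse annotation release 21 on GRCm38, from which positions were taken.

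Depth differed between libraries. Total UMIs were 73072964 for sham, 79866269 and 18282841 for day 4 control replicates 1 and 2, and 90411314 and 84219068 for day 4 cKO replicates 1 and 2. A barcode was called a cell if its UMI count reached 1/10 of the 99th percentile of the 3000 barcodes with most UMIs (4333.8 to 9633.6 UMIs), if it had at least 500 detected genes and if at most 20% of its UMIs were mitochondrial. Doublets were called per library with Scrublet in scanpy 1.11.5 at its own threshold and removed, 100 of 10114 cells (0.989%), with 12 in sham, 77 and 2 in day 4 control and 2 and 7 in day 4 cKO. Cells kept numbered 1877 in sham, 3179 and 618 in day 4 control and 2175 and 2165 in day 4 cKO, with median depths of 18566, 11239, 10614, 18109 and 12551 UMIs in the same order.

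Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes (chosen with library as batch), 30 principal components, 15 nearest neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1.0 gave 34 clusters without batch integration. No cell annotation was used; clusters were named from fixed marker sets of neuronal, glial, vascular, fibroblast, immune, ependymal and erythroid types, and a name ending in "-like" rests on those markers alone. A cluster counted as neuronal if the mean log2 ratio of its pan-neuronal markers to their mean over clusters exceeded -0.25, and took the class whose markers were detected in the largest share of its cells. Clusters with fewer than 3 markers each detected in 25% of cells, or with leading genes of another class, got no class. Pan-neuronal clusters whose non-neuronal markers exceeded 0.5 on the same scale were left unnamed. Both limits, -0.25 and 0.5, were set after the clusters were seen, and the second left out 1 cluster with 0, 2, 0, 19 and 2 cells in sham, day 4 control replicates 1 and 2 and day 4 cKO replicates 1 and 2. Of the 34 clusters, 20 were neuronal. A neuronal cluster led by Wfs1 and Lamp5 mixed markers of both classes, so it entered the comparison of all neurons only. It held 10.3% of sham neurons, 6.07% and 12.2% of day 4 control neurons and 2.65% and 11.3% of day 4 cKO neurons.

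UMI counts were summed per library over all neurons, over glutamatergic-like and over GABAergic-like cells, since cells are not replicates. The sums of the 5 libraries were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, TMM factors, filterByExpr), all in 1 fit with a coefficient per group, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A gene rose or fell where it passed. Levels are CPM, the UMIs of a gene scaled to a common total per library and class. Whether an effect differed between glutamatergic-like and GABAergic-like cells was tested with limma 3.58.1 on each library's difference in log2 CPM (prior count 2). The 20 gene lists were tested in all neurons with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's own genes move one way on balance. List p-values were adjusted over the 20 lists. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. A count of 0 was set against a floor of 3 UMIs.

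The named genes followed 1 rule. After Padi4 came up to 10 genes per direction (5 in the classes) with the largest log2 fold change among those that passed, with a mean of at least 20 CPM, no overlap between the groups' libraries, a neuronal level at or above that of non-neuronal cells, and no mitochondrial, Gm-number or Rik symbol. Where fewer than 5 passed, the genes of lowest p filled the list and are said not to pass. Results of some genes that the rule or the lists would name are not reported here. For each gene list the members with the lowest p, up to 4, could be named. Groups, comparisons, tests, markers, gene lists, this rule and most alternatives were fixed before the data were examined.

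The tests of genes, of class differences and of gene lists in neurons were tested on simulated counts for the real genes, with means and library sizes as measured and 100 genes changed at each of 2 fold sizes. In all neurons, the comparison of day 4 control with sham (16050 genes) recovered 11% of genes changed 2-fold and 89% of those changed 4-fold, and the comparison of day 4 cKO with day 4 control (16064 genes) recovered 32% and 98%. In glutamatergic-like cells these shares were 14% and 88% (15151 genes) and 30% and 97% (15124 genes). In GABAergic-like cells they were 30% and 95% (13285 genes) and 47% and 99% (13307 genes). Unchanged genes made up 15 of 115, 14 of 144, 14 of 116, 11 of 138, 24 of 149 and 6 of 152 calls in the same order, which for most lies above the nominal 5%. The class-difference test recovered 8% and 50% (12980 genes) for stroke and 8% and 80% (12988 genes) for the knockout, and called 10 unchanged genes in each. A list raised 1.5-fold was called in both comparisons (16495 genes), and 0 of the 19 unchanged lists were. Each gene was drawn independently, so this cannot show how often camera calls unchanged lists whose genes move together. Libraries were drawn independently too, without the likeness of same-numbered libraries described below. For the knockout in all neurons, 4.62% of unchanged simulated genes had an edgeR unadjusted p under 0.05, against 1.52% of the real genes. The recovery and false calls above may therefore not hold for the real knockout test. Cell calling, doublet removal, clustering and naming and the tests in oligodendrocyte-like cells were not simulated.

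The alternatives fixed beforehand were DESeq2 1.42.0 (Wald test), RLE size factors, no filter on low counts, a mean of at least 20 CPM, genes at least as high in neurons (or in the class) as in non-neuronal cells, a prior count of 0.5, a fixed minimum of 1000 UMIs per cell, a mitochondrial limit of 10% or none, doublets kept, Leiden resolution 2.0, clustering each library on its own, thinning to the smallest library, fits of only the libraries compared, the replicate number as a block, and leaving out each library of a group of 2. Chosen after the data were seen were a doublet score threshold of 0.2 in every library, clustering without Slc17a7 and Slc32a1, equal numbers of cells per cluster from every library, and neuron clusters at or above the library's median depth. Free RNA was measured in the barcodes ranked 10000 to 50000 by UMIs. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.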

Results

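Single-cell RNA profiles were collected from sorted mouse cortical neurons after ischemic stroke or sham surgery, in animals with or without a neuron-specific deletion of Padi4. Padi4 encodes a peptidylarginine deiminase, an enzyme that converts arginine in histones and other proteins to citrulline. The design asked what a stroke changes in neurons beside the infarct and what the loss of Padi4 in neurons changes there. One sham library, 2 day 4 control libraries and 2 day 4 cKO libraries held 18282841 to 90411314 UMIs each, and 10014 cells were kept, 5563 of them neurons. Neurons numbered 1424 in sham, 989 and 485 in day 4 control replicates 1 and 2, and 604 and 2061 in day 4 cKO replicates 1 and 2, and their median depth ranged from 11709 to 24560 UMIs.

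Although the sort selected Thy1-positive cells and excluded glial and vascular surface markers, the libraries differed in how neuronal they were. Neurons made up 75.9% of sham cells (95% interval 73.9 to 77.8), 31.1% (29.5 to 32.8) and 78.5% (75 to 81.7) of day 4 control cells and 27.8% (25.9 to 29.7) and 95.2% (94.2 to 96.1) of day 4 cKO cells. The sham value depended on the depth required of a cell, since at a fixed minimum of 1000 UMIs neurons made up 47.8% of sham cells (46.2 to 49.4). The spread of the neuronal share within each day 4 group exceeded the difference between the groups. With 2 libraries in each, the smallest p that a two-sided exact permutation test can give is 0.333. Oligodendrocyte-like cells, named from myelin genes such as Mbp and Mog, made up 13.6% of sham cells, 47.8% and 11.3% of day 4 control cells and 51.8% and 1.76% of day 4 cKO cells. Astrocyte-like cells made up 5.33% of sham (100 of 1877 cells), and 0 were found in the day 4 libraries, which allows shares of up to 0.116% to 0.595%. At a fixed minimum of 1000 UMIs the sham shares were 25.6% for astrocyte-like (986 of 3847 cells) and 8.94% for oligodendrocyte-like cells, and astrocyte-like cells made up 0.162% to 0.517% of the day 4 libraries. Most neurons were glutamatergic-like, with 1018 cells in sham, 668 and 300 in day 4 control and 376 and 1463 in day 4 cKO. GABAergic-like cells numbered 259, 261, 126, 212 and 365 in the same order. Glutamatergic-like cells came in part from different clusters in different libraries. A cluster led by Rorb, Hpca and Hopx drew 229 of its 230 cells from day 4 cKO replicate 2. Another, led by Nr4a2, Gnb4 and Oprk1, drew 80 of its 95 cells from day 4 control replicate 1.

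**Figure D1:**
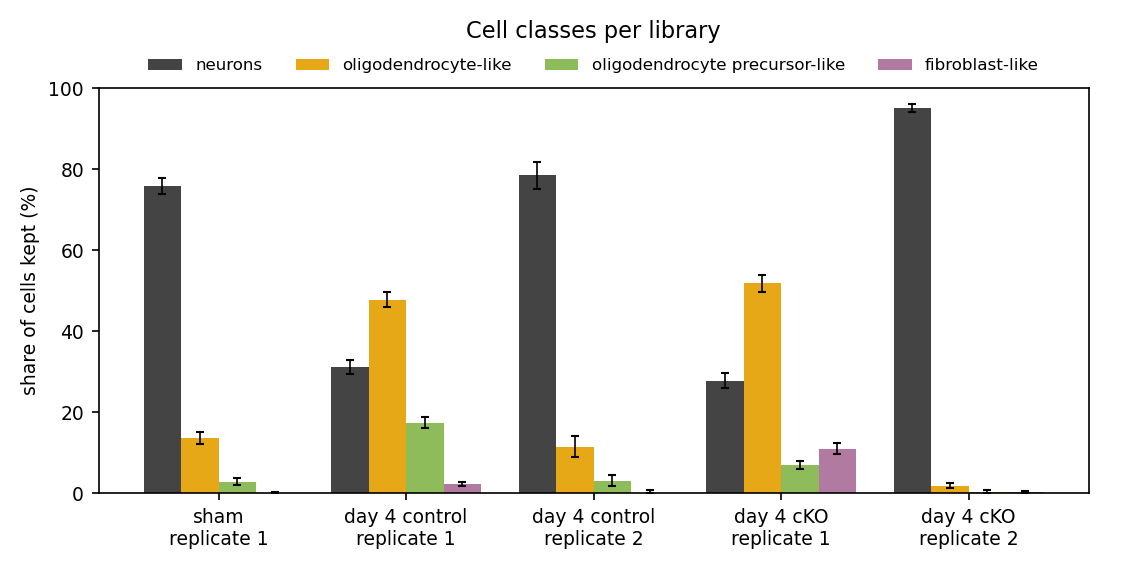
Share of the cells kept (%, vertical axis) that was named neuronal, oligodendrocyte-like, oligodendrocyte precursor-like or fibroblast-like in each of the 5 libraries (horizontal axis), with exact 95% binomial intervals as error bars. Replicate 1 of both day 4 groups held 31.1% and 27.8% neurons, and the other 3 libraries held 75.9% to 95.2%.

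Padi4 RNA (chromosome 4, 140745865 to 140774236, minus strand, GRCm38) was close to undetectable in every library. Neurons carried 1 UMI in sham, 2 and 0 UMIs in day 4 control and 0 and 1 UMIs in day 4 cKO, all below the floor of 3 UMIs per library. That floor corresponds to 0.0763, 0.151, 0.363, 0.187 and 0.0773 CPM in the same order. A loss of Padi4 RNA was therefore not detectable at this depth. Tags at the 3' end can lie outside the deleted exons, which are not given in the sources used here, so these counts check neither the deletion nor the labels. Pla2g2e, a secreted phospholipase of the same list, had 0 UMIs in the neurons of all 5 libraries.

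The vesicular transporter genes at whose loci Cre was placed were lower in the knockout. Slc32a1 (chromosome 2, 158610767 to 158615748) encodes the transporter that loads GABA and glycine into synaptic vesicles. In GABAergic-like cells it fell from 619 ± 13.1 CPM (SD, n = 2) in day 4 control to 126 ± 39.5 CPM (SD, n = 2) in day 4 cKO. Its log2 fold change was -2.24 (SE 0.24, adjusted p = 0.0039 in edgeR's quasi-likelihood test). Both cKO libraries, at 98.5 and 154 CPM, lay below the sham level of 519 CPM too. In all neurons it fell by 2.31 on the log2 scale (SE 0.23, edgeR adjusted p = 0.031). Slc17a7 (chromosome 7, 45163949 to 45176142), the vesicular glutamate transporter of most cortical excitatory neurons, stood at 923 ± 44.9 CPM (SD, n = 2) in the glutamatergic-like cells of day 4 control and 381 ± 45.8 CPM (SD, n = 2) in those of day 4 cKO, a log2 fold change of -1.21 (SE 0.22). That difference did not pass over all genes in edgeR (adjusted p = 1). It passed in DESeq2 (adjusted p = 0.02) and in edgeR with no filter on low counts (adjusted p = 0.0087), the lowest over its alternatives without the replicate block, whose highest was 1. The GABA-synthesising enzymes Gad1 and Gad2, in contrast, had log2 fold changes of -0.15 (SE 0.20) and 0.04 (SE 0.21) in GABAergic-like cells. Both transporter genes served as cluster markers. Clustering and naming the cells without them, a check chosen after seeing the data, gave the same values, -2.24 for Slc32a1 and -1.21 for Slc17a7. The call of Slc32a1 in GABAergic-like cells held in all 21 alternatives (adjusted p 2.9e-19 to 0.02), and that in all neurons in 17 of 21 (7.7e-15 to 0.076, the highest without day 4 control replicate 2). No library carried Cre together with an intact Padi4 gene. These levels count tags at the 3' end, so a change at the 3' end of the 2 transcripts was not told apart from less RNA. Of 388 tested genes within 20 Mb of Slc17a7, 2.58% had an unadjusted p under 0.05 in all neurons, against 1.48% elsewhere (odds ratio 1.76, 95% interval 0.83 to 3.34). Around Slc32a1 both shares were 1.5% (odds ratio 1.00, 0.32 to 2.38).

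**Figure D2:**
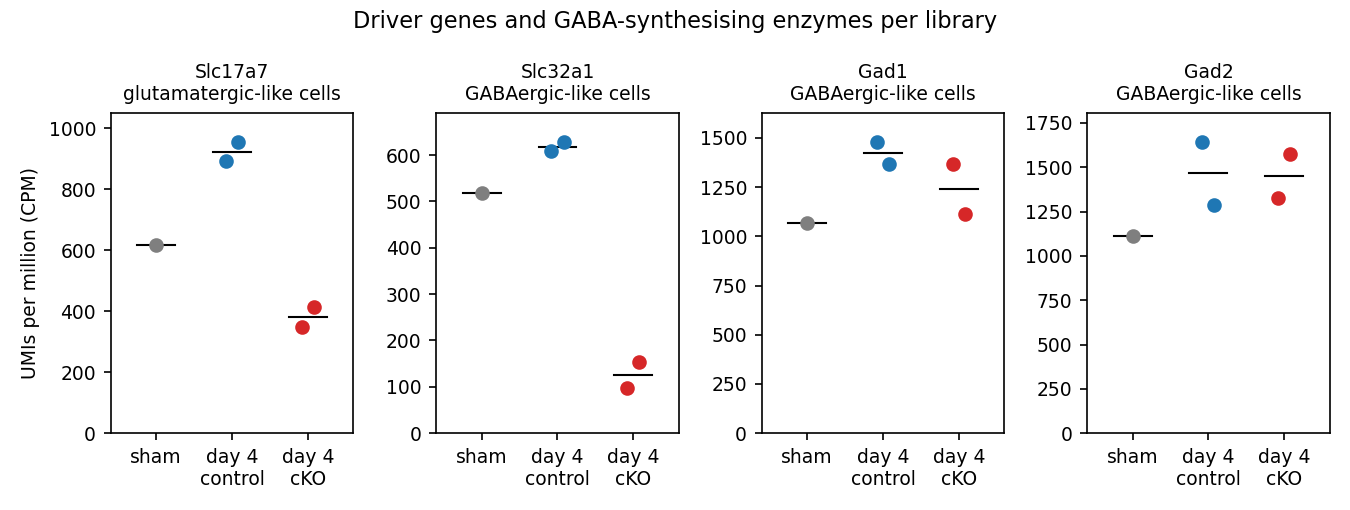
Levels of Slc17a7 in glutamatergic-like cells and of Slc32a1, Gad1 and Gad2 in GABAergic-like cells (CPM, vertical axes from 0), with a point per library and a line at each group mean. Day 4 cKO libraries hold 98.5 and 154 CPM of Slc32a1 against 609 and 628 CPM in day 4 control, and 349 and 413 CPM of Slc17a7 against 891 and 954 CPM.

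Comparing day 4 control with sham asked how neurons beside an infarct differ from sham neurons, whose label gives no day after surgery. Interferon-response and antigen-presentation genes, which cells switch on against viruses and in inflamed tissue, were higher in day 4 control neurons. All 25 tested members were higher, with a median log2 fold change of 2.08, or 2.08 with Usp18, which had 0 UMIs in sham, at its bound. The list passed camera at its preset correlation (adjusted p = 1.8e-25) and did not pass in 2 other tests (adjusted p = 0.38 with an estimated correlation, fry adjusted p = 0.17). No member passed over all 16495 genes in edgeR, and 16 rose when adjusted over the list alone. Among them Ifit1, which binds viral RNA, went from 0.61 CPM in sham to 9.48 and 14.5 CPM (log2 fold change 4.16, SE 0.52, edgeR list-alone adjusted p = 5.4e-04). Bst2 (tetherin, which holds viruses at the cell surface) went from 2.01 to 10.7 and 11.1 CPM (edgeR list-alone adjusted p = 0.0035). In day 4 cKO neurons the levels were 9.36 and 9.17 CPM for Ifit1 and 7.86 and 10.7 CPM for Bst2. H2-D1 and H2-K1 belong to a family of near-identical genes, so how their reads were divided is uncertain. Of the 25 members 24 had a higher level in non-neuronal than in neuronal cells, and the neuronal share was 31.1% in day 4 control replicate 1 and 78.5% in replicate 2. Summed microglia markers in neurons were 20.4 CPM in sham and 30.4 and 18.9 CPM in day 4 control, and summed oligodendrocyte markers were 150 CPM and 383 and 89.6 CPM. Summed fibroblast markers were higher in both day 4 control libraries, at 3.99 CPM in sham neurons and 59.5 and 33.1 CPM in day 4 control neurons.

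RNA made from the mitochondrial genome was higher in day 4 control neurons, whereas nuclear genes of the same respiratory chain were lower. All 13 mitochondrially encoded genes were higher, with a median log2 fold change of 1.58, and 11 of them had a higher level in non-neuronal than in neuronal cells. The list passed camera (adjusted p = 8.5e-24) and did not pass in the others (adjusted p = 0.25 with an estimated correlation, fry adjusted p = 0.094). No member passed over all genes in edgeR, and 12 rose when adjusted over the list alone. mt-Nd2 and mt-Nd5, subunits of complex I, went from 436 to 2011 and 1908 CPM and from 181 to 596 and 547 CPM, and mt-Atp6, of the ATP synthase, from 2417 to 11129 and 9420 CPM. The nuclear-encoded oxidative phosphorylation genes were lower in 34 of 39 members, with a median log2 fold change of -0.47 (camera adjusted p = 1.7e-09, adjusted p = 0.79 with an estimated correlation, 0 past the threshold when adjusted over the list alone). Examples are Cycs (cytochrome c), at 427 CPM in sham and 207 and 277 CPM in day 4 control, and Sdhb, a subunit of succinate dehydrogenase, at 276 CPM and 148 and 203 CPM. The mitochondrial share of UMIs in the median neuron was 1.02% in sham, 3.23% and 3.81% in day 4 control and 2.96% and 4.49% in day 4 cKO. Neurons in clusters below the median depth of their library made up 26.7% of sham, 27.7% and 44.3% of day 4 control and 8.77% and 52.5% of day 4 cKO neurons.

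**Figure D3:**
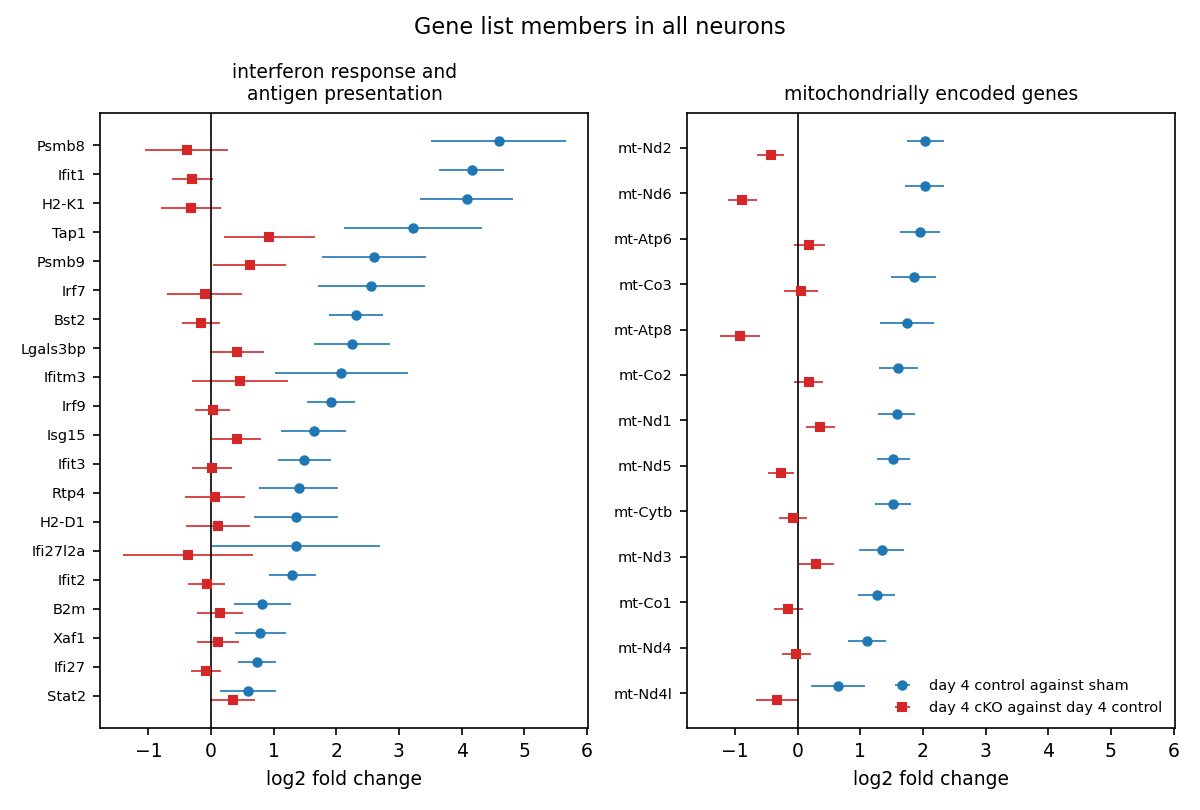
Log2 fold changes (horizontal axis) in all neurons of the interferon-response and antigen-presentation genes with more than 3 UMIs in sham (20 of these 21 are drawn, and 25 were tested) and of the 13 mitochondrially encoded genes, as points with standard errors, for day 4 control against sham (circles, 1 sham and 2 day 4 control libraries) and day 4 cKO against day 4 control (squares, 2 libraries each). All circles lie above 0, and the squares lie on both sides of 0.

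Ribosomal protein and immediate early genes passed camera as lower. Of 84 ribosomal protein genes 63 were lower (median log2 fold change -0.18, camera adjusted p = 0.0039, adjusted p = 0.79 with an estimated correlation, 0 when adjusted over the list alone), and 80 had a higher level in non-neuronal than in neuronal cells. That call rested on day 4 control replicate 1, since without it the camera adjusted p was 0.95, the highest of its alternatives (lowest 1.4e-10). Of 20 immediate early genes, which neurons induce within minutes of firing, 16 were lower (median -0.24, camera adjusted p = 0.014, adjusted p = 0.79 with an estimated correlation), and 13 had a higher level in non-neuronal cells. Among members at least as high in neurons the list did not pass (camera adjusted p = 0.084). The only member past the threshold when adjusted over the list alone rose: Fosb, a subunit of the AP-1 transcription factor, went from 16.4 to 85.7 and 49.5 CPM (edgeR list-alone adjusted p = 0.0099). The list turned upward, without passing, when day 4 control replicate 2 was left out (camera adjusted p = 0.64, with 1.6e-08 to 0.88 over its alternatives).

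Genes of synapses, axons and stress pathways did not pass as lists. Of 28 axon injury and regeneration genes 16 were higher (camera adjusted p = 0.95), and 1 rose when adjusted over the list alone, Stat3, a cytokine-activated transcription factor that went from 12 CPM to 37.6 and 34 CPM (edgeR list-alone adjusted p = 0.049). Of 25 presynaptic release genes 14 were higher (camera adjusted p = 0.95), and 1 fell when adjusted over the list alone, Stx1a, a membrane protein of the vesicle fusion machinery, with a log2 fold change of -1.13 (SE 0.24, edgeR list-alone adjusted p = 0.024). The presynaptic list had a median of 0.04 and a mean of 0.01 with camera pointing down, and the 28 postsynaptic genes a median of 0.04 and a mean of -0.01 with camera pointing down (adjusted p = 0.95). Endoplasmic reticulum stress genes (9 of 24 higher, camera adjusted p = 0.67) had a median of -0.08 and a mean of 0.01, and oxidative stress and metal-binding genes (9 of 21 higher, camera adjusted p = 0.68) a median of -0.05 and a mean of 0.18, both with camera pointing down. Of 25 chromatin and histone-modifying genes 19 were higher (median 0.22, camera adjusted p = 0.057). Camera adjusted p-values were 0.12 for cytoskeletal genes, 0.14 for glycolysis and hypoxia, 0.18 for heat shock, 0.2 for inflammatory cytokines, 0.26 for p53 targets, 0.27 for voltage-gated channels, 0.28 for cholesterol synthesis, 0.44 for peptidylarginine deiminases and lipid mediators, and 0.62 for growth factors. With an estimated correlation, adjusted p-values of the 15 lists were 0.79 to 0.98.

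Gene by gene, the contrast of day 4 control with sham passed for 0 of 16495 genes in edgeR (smallest adjusted p = 0.35). An unadjusted p under 0.05 was reached by 1062 genes (6.44%), where about 5% is expected with no change. DESeq2 called 39 higher and 13 lower. Low p-values among higher genes belonged to Nme7, a nucleoside diphosphate kinase family member (60.2 CPM in sham, 380 ± 78 CPM (SD, n = 2) in day 4 control, log2 fold change 2.54, SE 0.40), the histamine H3 receptor gene Hrh3 (21.7 and 64.8 ± 16.5 CPM), the mitochondrial leucyl-tRNA synthetase Lars2 (233 and 661 ± 62 CPM) and the receptor phosphatase Ptprm (12.9 and 33.3 ± 2.4 CPM). Among lower genes they belonged to the kinase Pak7 (174 and 40.8 ± 17.3 CPM), Itpka, a synaptic inositol kinase (315 and 139 ± 6.24 CPM), Stx1a (294 and 147 ± 2.09 CPM), the receptor-associated protein Ramp3 (48.7 and 21.3 ± 4.31 CPM) and the calcium-dependent kinase Camk4 (128 and 63.4 ± 4.38 CPM). None of these genes passed (edgeR adjusted p = 0.35 to 0.76). Some of them also set clusters apart. Nme7 was among the leading genes of 4 neuronal clusters, and Itpka, Stx1a and Camk4 were each among those of 1. The 4 clusters with Nme7 were shallow, at 0.58 to 0.79 of the library median depth, with median mitochondrial shares of 5.11% to 9.08%. With equal numbers of cells per cluster from every library, a setting chosen after seeing the data, log2 fold changes were 2.13 for Nme7, -0.94 for Itpka, -0.83 for Stx1a and -0.81 for Camk4. Without day 4 control replicate 1, edgeR called 3 genes.

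In GABAergic-like cells Nme7 (chromosome 1, 164304121 to 164437725) rose after stroke, from 81.3 CPM to 451 ± 33.1 CPM (SD, n = 2; log2 fold change 2.39, SE 0.32, edgeR adjusted p = 0.042). It was the only one of 13600 genes to pass, with 644 (4.74%) at an unadjusted p under 0.05 and 14 higher and 1 lower in DESeq2. Genes that did not pass included Pthlh, a parathyroid hormone-like peptide (83.4 CPM in sham and 26.3 ± 3.74 CPM (SD, n = 2) in day 4 control, log2 fold change -1.75, edgeR adjusted p = 0.095), the carbonic anhydrase Car4 (37.6 and 13.9 ± 6 CPM), the G-protein regulator Rgs10 (421 and 175 ± 63.4 CPM), the netrin receptor Unc5d (22 and 50.1 ± 3.13 CPM) and the calcium channel Cacna1e (29.8 and 62.9 ± 2.85 CPM). The Nme7 call was lost with a mitochondrial limit of 10% (edgeR adjusted p = 0.22) and when each library was clustered on its own (0.12), and held in 17 of 19 alternatives (1e-11 to 0.22). Nme7 was among the leading genes of 1 GABAergic-like cluster, at 0.65 of the library median depth and with a median mitochondrial share of 7.54%. With equal numbers of cells per cluster the log2 fold change of Nme7 was 2.31, a setting that does not match depth or mitochondrial share within a cluster. Leaving out day 4 control replicate 1 or 2 gave 29 or 38 genes.

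In glutamatergic-like cells 0 of 15574 genes passed in edgeR after stroke (smallest adjusted p = 0.63), 833 (5.35%) had an unadjusted p under 0.05, and DESeq2 called 25 higher and 7 lower. Nme7 again had the lowest p among higher genes (49.1 CPM in sham, 323 ± 77.4 CPM (SD, n = 2) in day 4 control), beside Hrh3 (19.5 and 53.7 ± 6.02 CPM) and the amino acid transporter-like Slc7a14 (34.8 and 83.4 ± 4.65 CPM). Calbindin, encoded by Calb1 (328 and 127 ± 9.39 CPM, log2 fold change -1.48, SE 0.27), Mpped1 (182 and 79.7 ± 5.2 CPM) and Pak7 (195 and 53 ± 26.5 CPM) led the lower genes. Calb1 was also among the leading genes of a cluster with 217 sham cells and 68 and 34 day 4 control cells, and its log2 fold change was -1.04 with equal numbers of cells per cluster. Leaving out day 4 control replicate 1 or 2 gave 13 or 24 genes. The effect of stroke was not shown to differ between the classes for any gene: of 13311 genes 0 passed in limma (410 at an unadjusted p under 0.05; this difference was not run in DESeq2). The lowest p belonged to B2m, the light chain of the antigen-presenting complex, with a log2 fold change of 0.56 in glutamatergic-like and 2.37 in GABAergic-like cells (limma difference -1.75, SE 0.18, adjusted p = 0.13). Without day 4 control replicate 1, control replicate 2 or cKO replicate 1, 24, 8 and 1 genes differed between the classes.

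Comparing day 4 cKO with day 4 control asked what losing Padi4 in neurons changes beside the infarct. In all neurons 0 genes rose and 2 of 16495 fell in edgeR, Slc32a1 and Gm10503, with 0 higher and 5 lower in DESeq2, which shared both. An unadjusted p under 0.05 was reached by 250 genes (1.52%), fewer than the 5% expected with no change. With the replicate number as a block, edgeR called many more genes in all neurons and in both classes, as given in the part on processing. Gm10503, which falls outside the rule for named genes and was chosen after its values were seen, is an antisense RNA on chromosome 17 (30920338 to 30963220, minus strand). It stood at 9.58 CPM in sham, 8.48 and 5.81 CPM in day 4 control and 0 and 0.0258 CPM in day 4 cKO (edgeR adjusted p = 0.012). Pooled over the libraries of a group, 217 UMIs in day 4 control against 1 UMI in day 4 cKO gave a ratio of 422 (exact 95% counting interval 75 to 16755). The locus overlaps the protein-coding genes Glp1r and Umodl1 and the noncoding AC165951.6 on the opposite strand and the noncoding AC174471.1 on its own strand, so the origin of its UMIs is uncertain. Whether control and cKO mice share a genetic background at this locus is not given in the sources used here, so a difference in haplotype was not separated from the deletion. The Gm10503 call ended when all libraries were thinned to the smallest (edgeR adjusted p = 0.054), and held in 19 of 20 alternatives (8.3e-24 to 0.054). Leaving out day 4 control replicate 1, control replicate 2, cKO replicate 1 or cKO replicate 2 gave 4, 1, 4 and 4 genes.

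Other genes with low p in the same comparison did not pass (edgeR adjusted p = 1). Necdin (Ndn), an imprinted gene of postmitotic neurons, stood at 343 ± 16.5 CPM (SD, n = 2) in day 4 control and 147 ± 17.6 CPM (SD, n = 2) in day 4 cKO, and Slc17a6, the vesicular glutamate transporter of thalamic and other neurons, at 35.4 ± 8.39 and 17.1 ± 2.22 CPM. Both genes lie within 20 Mb of the Slc17a7 driver locus on chromosome 7. Lypd1, which modulates nicotinic acetylcholine receptors, stood at 72.3 ± 6.2 and 40.7 ± 9.15 CPM. Higher in cKO were the keratin gene Krt12 (65.3 ± 2.07 and 109 ± 0.465 CPM, log2 fold change 0.80, SE 0.20), Armcx5 (88.2 ± 1.46 and 154 ± 47.8 CPM), the vesicle-trafficking GTPase Rab33a (64.3 ± 8.77 and 108 ± 24.8 CPM), Amn (21.4 ± 3.58 and 36.1 ± 0.554 CPM) and Pak7 (40.8 ± 17.3 and 78.2 ± 2.92 CPM). Krt12 stood at 111 CPM in sham, close to its cKO level, and was also among the leading genes of clusters led by Rorb.

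In GABAergic-like cells of the knockout 2 of 13600 genes fell and 0 rose in edgeR, with 338 (2.49%) at an unadjusted p under 0.05 and 0 higher and 3 lower in DESeq2. Beside Slc32a1, Ndn (chromosome 7, 62346569 to 62350262) fell from 545 ± 19.3 to 187 ± 33.7 CPM (SD, n = 2 each; log2 fold change -1.49, SE 0.21, edgeR adjusted p = 0.034). Ndn lies within 20 Mb of the Slc17a7 driver locus, and a flanking segment that differs between the genotypes was not ruled out. The chemokine Cxcl14 (1354 ± 80.9 and 751 ± 108 CPM), the relaxin receptor Rxfp1 (38.6 ± 7.29 and 19.8 ± 2.06 CPM) and the secreted factor Ndnf (65.7 ± 25.1 and 33.3 ± 6.69 CPM) were lower without passing, and Rprml (31.8 ± 2.89 and 73.8 ± 27.7 CPM), Armcx5 (80.3 ± 6.92 and 143 ± 42.4 CPM) and the transcription factor Tox3 (69.5 ± 4.84 and 114 ± 19.7 CPM) were higher without passing. Gm10503 had 22 UMIs in day 4 control and 0 in day 4 cKO, at least 13.3-fold lower against a floor of 3 UMIs over the group, and did not pass (edgeR adjusted p = 0.28). The Ndn call was lost without day 4 cKO replicate 1 (edgeR adjusted p = 0.13), with a minimum of 1000 UMIs (0.057) and with each library clustered on its own (0.12), and held in 18 of 21 alternatives (8.3e-08 to 0.13). Leaving out day 4 control replicate 1, control replicate 2, cKO replicate 1 or cKO replicate 2 gave 23, 5, 16 and 14 genes.

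In glutamatergic-like cells Gm10503 was the only gene of 15574 called (edgeR adjusted p = 0.041, 271 or 1.74% at an unadjusted p under 0.05, 0 higher and 2 lower in DESeq2). Its pooled UMIs were 187 in day 4 control and 1 in day 4 cKO (ratio 369, counting interval 65.4 to 14641). Neuropeptide Y (Npy) was higher in cKO without passing (22.1 ± 2.95 and 45.2 ± 6.62 CPM, SD, n = 2 each), as were Amn (17.7 ± 2.23 and 35.7 ± 0.782 CPM) and the nuclear receptor Rora (103 ± 12.2 and 158 ± 18.2 CPM). With equal numbers of cells per cluster the log2 fold change of Npy turned from 1.09 to -0.18. Ndn was lower (267 ± 3.59 and 135 ± 20.8 CPM), as was Mgat4c, a glycosyltransferase gene (55.3 ± 2.78 and 33.4 ± 2.61 CPM). The Gm10503 call held in 10 of 20 alternatives (adjusted p 9.2e-21 to 0.77). Leaving out day 4 control replicate 1, control replicate 2, cKO replicate 1 or cKO replicate 2 gave 6, 8, 0 and 0 genes. The effect of the knockout was not shown to differ between glutamatergic-like and GABAergic-like cells, with 0 of 13311 genes in limma (301 at an unadjusted p under 0.05, smallest adjusted p = 1; not run in DESeq2). Without day 4 control replicate 1, control replicate 2 or cKO replicate 1 there were 6, 4 and 1.

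Among the gene lists, those of ribosomal proteins and of nuclear-encoded oxidative phosphorylation passed camera as higher in day 4 cKO than in day 4 control neurons, and neither passed with an estimated correlation or in fry. Of 84 ribosomal protein genes 69 were higher (median log2 fold change 0.14, camera adjusted p = 7.1e-06, adjusted p = 0.87 with an estimated correlation, fry adjusted p = 0.98), with Rps15 at 319 and 286 CPM in day 4 control and 462 and 435 CPM in cKO. Of 39 oxidative phosphorylation genes 36 were higher (median 0.16, camera adjusted p = 7.8e-05, adjusted p = 0.87 with an estimated correlation, fry adjusted p = 0.98), with Ndufa4 at 1895 and 1994 CPM and 2455 and 2180 CPM. Of 21 oxidative stress and metal-binding genes 17 were higher (median 0.20, camera adjusted p = 0.0058, adjusted p = 0.87 with an estimated correlation, fry adjusted p = 0.014). Of 24 endoplasmic reticulum stress genes 16 were lower (median -0.16, camera adjusted p = 0.0091, adjusted p = 0.87 with an estimated correlation, fry adjusted p = 0.98), among them Pdia4, a chaperone that forms disulfide bonds, at 30.8 and 32.5 CPM in day 4 control and 20.3 and 16.8 CPM in cKO, and Xbp1, a transcription factor of the unfolded protein response, at 87.1 and 73.9 CPM and 55.5 and 55.1 CPM. In each of these 4 lists 0 members passed in edgeR, over all genes or adjusted over the list alone. A higher level in non-neuronal than in neuronal cells was found for 80 of the 84 ribosomal, 20 of the 24 endoplasmic reticulum stress, 16 of the 21 oxidative stress and 2 of the 39 oxidative phosphorylation genes, and the neuronal share was 31.1% and 78.5% in day 4 control and 27.8% and 95.2% in day 4 cKO. Among members at least as high in neurons, camera gave adjusted p = 0.29 for oxidative stress. In oligodendrocyte-like cells, whose lineage does not normally express the driver genes, 18 of 24 endoplasmic reticulum stress genes were lower in cKO (median -0.60, camera adjusted p = 1.1e-05, adjusted p = 0.61 with an estimated correlation). There 33 of 39 oxidative phosphorylation genes were higher (median 0.14, camera adjusted p = 0.0092, adjusted p = 0.75 with an estimated correlation). The genotypes filled oligodendrocyte-like clusters differently, and this was not separated from a change inside clusters. For example, a cluster led by Gdf15 and Tnfrsf12a held 281 and 9 day 4 control cells and 44 and 4 day 4 cKO cells. The calls in neurons depended on single libraries. Without day 4 control replicate 1, camera gave adjusted p = 0.61 and the opposite direction for ribosomal proteins, 0.82 for oxidative phosphorylation, 0.61 for endoplasmic reticulum stress and 0.077 for oxidative stress. Without day 4 cKO replicate 1 it gave 0.72 for oxidative phosphorylation and 0.078 for oxidative stress, and without cKO replicate 2 it gave 0.064 for endoplasmic reticulum stress. Over the alternatives of each list, adjusted p ranged from 1.5e-13 to 0.98 for ribosomal proteins, 2.4e-10 to 0.98 for oxidative phosphorylation, 3.4e-04 to 0.98 for endoplasmic reticulum stress and 0.0058 to 0.87 for oxidative stress. The number of lists called went from 4 to 9 without day 4 control replicate 2 and to 8 without cKO replicate 2. The day 4 control libraries entered both comparisons, so opposite directions in the 2 contrasts are not independent.

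Interferon-response genes were not called between the genotypes in neurons, with 16 of 25 higher in cKO (median log2 fold change 0.06, camera adjusted p = 0.35, adjusted p = 0.89 with an estimated correlation). Among presynaptic release genes, 1 of 25 fell over all genes and 2 when adjusted over the list alone, Slc32a1 (edgeR list-alone adjusted p = 9.3e-05) and Slc17a7 (0.011), while the list did not pass (camera adjusted p = 0.31; median 0.01, mean -0.14, camera pointing down). Of 8 tested peptidylarginine deiminase and lipid mediator genes 4 were higher (camera adjusted p = 0.58), and Padi4 itself was too low to be tested. Camera adjusted p-values of the other lists were 0.069 for cholesterol synthesis (5 of 22 higher), 0.087 for p53 targets (15 of 21 higher), 0.11 for immediate early genes (6 of 20 higher), 0.14 for mitochondrially encoded genes (5 of 13 higher), 0.31 for postsynaptic genes and for heat shock, 0.54 for voltage-gated channels and for glycolysis and hypoxia, 0.63 for inflammatory cytokines, 0.83 for growth factors, and 0.93 for axon injury, cytoskeletal and chromatin genes. With an estimated correlation these adjusted p-values were 0.87 to 0.98, and no member of these lists passed when adjusted over the list alone. The sign differed within 3 of these: growth factors had a median of 0.05, a mean of -0.07 and camera pointing down, glycolysis and hypoxia a median of 0.05, a mean of -0.03 and camera pointing up, and cytoskeletal genes a median of -0.01 with camera pointing up.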

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

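The tests on free RNA and on shared sequence were set before their results were seen, and the other tests in this part were chosen afterwards.

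Cells that the sort was set to exclude appeared in some day 4 libraries at shares above the 95% interval of the sham library. Oligodendrocyte-like cells made up 47.8% of day 4 control replicate 1 and 51.8% of day 4 cKO replicate 1, against 13.6% of sham (12.1 to 15.2), although O4-positive cells were excluded. Oligodendrocyte precursor-like cells made up 17.3% and 6.9% of the same 2 libraries, against 2.82% of sham (2.12 to 3.68), although CD140a-positive cells were excluded. Fibroblast-like cells made up 2.26% and 11% of them, against 0 of 1877 sham cells, which allows a share of up to 0.196%. Mural-like cells made up 6.47% of day 4 control replicate 2, against 1.65% of sham (1.12 to 2.34), although CD140b-positive cells were excluded. The sham shares depended on the depth required of a cell. At a fixed minimum of 1000 UMIs they were 8.94% (8.06 to 9.89) for oligodendrocyte-like, 7.02% (6.23 to 7.87) for oligodendrocyte precursor-like, 0.182% (0.0732 to 0.375) for fibroblast-like and 4.47% (3.84 to 5.17) for mural-like cells. The day 4 shares above were then 41.8% and 45.8% for oligodendrocyte-like, 18.1% and 9.57% for oligodendrocyte precursor-like, 1.48% and 5.68% for fibroblast-like and 9.24% for mural-like cells, each still above the sham interval. With each library clustered on its own, fibroblast-like cells made up 4.74% of day 4 cKO replicate 1.

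Slc32a1 and Slc17a7 were lower in day 4 cKO neurons. Another mix of glutamatergic-like and GABAergic-like cells is argued against by the change inside each class, -1.21 for Slc17a7 in glutamatergic-like cells (SE 0.22) and -2.24 for Slc32a1 in GABAergic-like cells (SE 0.24). A segment of chromosome carried along with each driver stays open. Around Slc17a7 the odds ratio of an unadjusted p under 0.05 among genes within 20 Mb was 1.76 in all neurons (95% interval 0.83 to 3.34, Fisher's exact p = 0.088), 1.59 in glutamatergic-like (0.75 to 3.0) and 1.16 in GABAergic-like cells (0.52 to 2.27), and around Slc32a1 1.00 in all neurons (0.32 to 2.38, Fisher's exact p = 1) and 1.18 in GABAergic-like cells (0.50 to 2.39), intervals that reach above 2, with 0.72 in glutamatergic-like cells (0.19 to 1.90). A candidate explanation is that the Cre insertion lowers the RNA, or only the count of 3' tags, of the gene it sits in. Gad2 had a log2 fold change of 0.04 (SE 0.21) in GABAergic-like cells. An effect of the insertion cannot be told apart from an effect of Padi4 loss, because both occur in the same 2 libraries.

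Interferon-response and antigen-presentation genes were higher in day 4 control neurons than in sham neurons. Free RNA in the amount that background droplets hold was 1.33% and 0.499% of neuron UMIs in day 4 control replicates 1 and 2. That amount is argued against as the main source, as it would give 3.19% and 0.527% of the median member's level, with 44.7% for the highest member. Summed oligodendrocyte markers, at 383 and 89.6 CPM in neurons and 4373 and 1230 CPM in background droplets, exceed what it would give, so more RNA may be carried over. RNA from attached non-neuronal cells was not tested. A sham library that differs for reasons other than surgery stays open, since with an estimated correlation and 1 sham library the adjusted p was 0.38. The stroke itself is the biological reading named by the design and may account for the pattern, but it cannot be told apart from such a difference with 1 sham library.

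Mitochondrially encoded genes, Lars2 and Nme7 were higher together in day 4 control neurons. For the mitochondrially encoded genes, a larger share of neurons in shallow clusters as the whole cause is argued against. In the deeper neuron clusters they kept a median log2 fold change of 1.42 (quartiles 1.13 and 1.66), against 1.58 in all neurons. Those clusters were not matched for depth, with medians of 31250 UMIs in sham and 22158 and 20816 in day 4 control. Lars2 and Nme7 were not part of this test. Reads shared between the mitochondrial genome and Lars2 or Nme7 are argued against for annotated exons, as 0 stretches of 25 bases were shared with 9 Lars2 and 10 Nme7 transcripts. The stroke, as the biological reading, and other differences of the lone sham library stay open and untested.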

How the results depend on the processing

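Tests on a doublet score of 0.2, on clustering without Slc17a7 and Slc32a1, on equal numbers of cells per cluster and on deeper neuron clusters were chosen after the results were seen. RLE size factors, the doublet score and clustering without the 2 transporter genes left every result they were run on at its direction and side of the threshold, or within its spread. Over all alternatives, 4375 values of single genes, lists and shares of other classes stayed so, 104 gained a call, 48 lost it, 12 moved and 21 turned direction, and of counts of calls and neuronal shares 129 stayed within their bounds and 79 moved. The cause was not tested unless a setting tested fewer genes or used fewer libraries by construction. Depth differed between the sums: neurons of day 4 control replicate 2 held 8255713 UMIs, against 16031965 to 39336248 in the other libraries, and thinning to the smallest library ended the call of Gm10503 in all neurons.

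In DESeq2 the counts were 52 in all neurons, 32 in glutamatergic-like and 15 in GABAergic-like cells for stroke, and 5 in all neurons and 2 in glutamatergic-like cells for the knockout. With no filter they were 133, 79 and 64 for stroke and 15, 12 and 23 for the knockout. Genes at or above 20 CPM gave 1 in all neurons and 0 in glutamatergic-like cells for the knockout, as did thinning to the smallest library, a mitochondrial limit of 10%, the fit of only the 4 day 4 libraries and the deeper neuron clusters. In glutamatergic-like cells the knockout count was also 0 with no mitochondrial limit, at Leiden resolution 2.0, with each library clustered on its own and with equal numbers of cells. Stroke in GABAergic-like cells gave 2 genes among those at least as high in the class as in non-neuronal cells, 2 at 1000 UMIs, 2 with doublets kept, 2 with equal cells, 0 at a 10% mitochondrial limit and 0 with each library clustered on its own. The knockout count in GABAergic-like cells was 1 at 1000 UMIs. The 3 libraries of the control genotype alone gave 3 genes in all neurons and 5 in GABAergic-like cells. Equal cells gave 4 genes whose stroke effect differed between classes.

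Lists called numbered 0 for stroke and 0 for the knockout with an estimated correlation, and 0 and 1 with fry. Among genes at least as high in neurons as in non-neuronal cells they numbered 1 and 2, but lists left with fewer than 5 members were not run there. These included the interferon, mitochondrially encoded and ribosomal lists called for stroke and the ribosomal and endoplasmic reticulum stress lists called for the knockout, so the lower counts say nothing of those calls. Of the called lists that were run, oxidative phosphorylation passed in both comparisons, and immediate early genes for stroke (adjusted p = 0.084) and oxidative stress for the knockout (adjusted p = 0.29) did not. The neuronal share in sham was 47.8% at 1000 UMIs, 70.4% at resolution 2.0 and 67% with libraries clustered apart. At 1000 UMIs it was 34.4% and 69.6% in day 4 control replicates 1 and 2 and 32.9% and 91.7% in day 4 cKO replicates 1 and 2, and in control replicate 1 it was 27.7% at the 10% limit and 28.8% at resolution 2.0.

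Leaving out 1 library at a time gave, for stroke, 0 to 3 genes in all neurons, 13 to 24 in glutamatergic-like and 29 to 38 in GABAergic-like cells, and for the knockout 1 to 4, 0 to 8 and 5 to 23. Class differences ranged from 0 to 24 genes for stroke and 0 to 6 for the knockout, and lists called from 5 to 6 and from 3 to 9. Apart from the lists of immediate early genes and of ribosomal proteins, the results whose direction turned with a library left out had not passed. For stroke, leaving out control replicates took the log2 fold change of Fads1 from -0.03 to 0.43 and that of Slc7a11 from -0.42 to 2.23, and the camera adjusted p of immediate early genes from 1.6e-08 to 0.64, upward at 0.64. For the knockout, the log2 fold changes ranged from -0.13 to 0.46 for Fads1 (with -0.02 without control replicate 1), -0.06 to 1.68 for Tgfb2, -1.21 to 0.05 for Hsph1, -2.05 to 0.37 for Bag3, -0.42 to 1.78 for Tap1, -0.03 to 1.52 for Psmb9 and -0.35 to 0.81 for Stat2. They ranged from -0.66 to 0.03 for Insig1, -0.72 to 0.04 for Tmsb10, -0.09 to 0.49 for Tet2 and -0.58 to 0.07 for Smarca4 (with 0.02 without cKO replicate 2). Slc32a1 in glutamatergic-like cells ranged from -1.80 to 0.27 and Slc17a7 in GABAergic-like cells from -1.08 to 0.41. The camera adjusted p of ribosomal proteins ranged from 1.5e-13 to 0.61, downward at 0.61. With equal cells, Elovl5 for stroke was -0.16 and Npy in glutamatergic-like cells of the knockout -0.18.

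With the replicate number as a block in the 4 day 4 libraries, the replicate block gave 97 genes in all neurons, 100 in glutamatergic-like and 74 in GABAergic-like cells and 8 lists for the knockout. The difference between replicates 1 and 2 correlated across 16495 genes between the groups (r = 0.469; genes are not independent replicates). Libraries of the same number correlated at 0.985 and 0.977, and those of the same group at 0.965 and 0.968. Libraries of the same number were thus more alike than those of the same group, in these values and in neuronal share. With 2 pairs and no batch in the labels, what they share is not known, and the main fit leaves it unmodelled. The number of genes called for the knockout depends on that choice, and the blocked fit has little left from which to estimate the spread.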

Other observations

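All tests in this part were chosen after the data were seen, apart from the gene lists, which were fixed before.

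In oligodendrocyte-like cells, which passed the sort in every library, more genes were called between day 4 control and sham than in neurons. The sums of replicate 2 rested on few cells, 70 in day 4 control and 38 in day 4 cKO. Whether the effects themselves differed between these cells and neurons was not tested. Of 11939 genes 117 rose and 61 fell in edgeR (smallest adjusted p = 1.4e-04), and DESeq2 called 147 higher and 71 lower. Serpina3n, a secreted protease inhibitor of reactive glia, rose from 3.19 CPM in sham to 719 and 1031 CPM in day 4 control (log2 fold change 7.93, SE 0.61). The complement component C4b rose from 3.51 to 246 and 333 CPM, and Socs3, an inhibitor of cytokine signalling, from 3.19 to 126 and 109 CPM. Gadd45b, a stress-induced regulator, rose from 13.4 to 659 and 554 CPM. The protease gene Klk8, with 0 UMIs in sham, was at least 253-fold higher against a floor of 3 UMIs in that library, and the calcium-binding S100a4 at least 72.5-fold higher. The genes that fell included Jph4 (336 to 42.3 and 38.9 CPM), Desi1 (891 to 244 and 170 CPM) and Pak7 (166 to 29.3 and 33.7 CPM). Slc1a2, Sparcl1 and Clu, abundant in astrocytes, fell as well, and astrocyte-like cells made up 5.33% of sham cells, or 25.6% at a fixed minimum of 1000 UMIs, where they were 0.162% to 0.517% of the day 4 libraries. Leaving out day 4 control replicate 1 gave 77 genes, leaving out control replicate 2 gave 471, and leaving out cKO replicate 2 gave 783.

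Of the 20 gene lists 10 passed camera for stroke in these cells, and none of the 10 passed with an estimated correlation. Ribosomal proteins had the lowest camera p, with 82 of 83 genes higher (median log2 fold change 0.75, camera adjusted p = 2.4e-21, adjusted p = 0.35 with an estimated correlation), 0 of them past the threshold over all genes in edgeR and 4 when adjusted over the list alone. Of 24 endoplasmic reticulum stress genes Trib3, Asns and Nupr1 rose, and 11 when adjusted over the list alone (median 1.06, camera adjusted p = 1.6e-07, adjusted p = 0.23 with an estimated correlation). This list and that of glycolysis and hypoxia, which did not pass camera (adjusted p = 0.069), were the only ones to pass fry (adjusted p = 0.042 for each). Of 24 axon injury and regeneration genes 8 rose over all genes, among them Atf3, Cd44 and Socs3, and 12 rose and 1 fell when adjusted over the list alone (median log2 fold change 1.88, or 1.79 with members at 0 at their bound; camera adjusted p = 7.3e-13, adjusted p = 0.23 with an estimated correlation). Of 23 interferon-response genes 4 rose, B2m, Irf9, H2-K1 and H2-D1, and 17 when adjusted over the list alone (median 3.89, or 2.26 with the 8 members at 0 in sham at their bound; camera adjusted p = 5e-11, adjusted p = 0.35 with an estimated correlation). Among 19 immediate early genes Junb, Fos, Egr3 and Nr4a1 rose, and 13 when adjusted over the list alone (camera adjusted p = 1e-11, adjusted p = 0.35 with an estimated correlation). All 22 cholesterol synthesis genes were lower (median -1.03), Idi1 fell over all genes and 8 fell when adjusted over the list alone (camera adjusted p = 3.4e-10, adjusted p = 0.23 with an estimated correlation). Fry adjusted p-values were 0.11 for axon injury, 0.33 for interferon response, 0.21 for immediate early genes and 0.11 for cholesterol synthesis. Day 4 libraries drew many of these cells, though not all, from other clusters than sham did. A cluster led by Ptgds and Mal held 250 of the 255 sham cells, and also 404 and 13 day 4 control cells and 41 and 3 day 4 cKO cells. In contrast, 3 clusters, led by Gjb1 and Cd63, by Trf and Klk6, and by Gdf15 and Tnfrsf12a, held 0 sham cells.

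Between day 4 cKO and day 4 control, 1 gene fell in oligodendrocyte-like cells and 0 rose in edgeR, with 173 at an unadjusted p under 0.05 and 1 higher and 1 lower in DESeq2. It was the haemoglobin gene Hbb-bs (chromosome 7, 103826534 to 103828096), at 1.28 CPM in sham, 35.2 and 29.8 CPM in day 4 control and 0.49 and 0 CPM in day 4 cKO (edgeR adjusted p = 0.0042). The value of 0 comes from a library with 38 oligodendrocyte-like cells. In neurons Hbb-bs stood at 43.9 CPM in sham, 0.953 and 34.2 CPM in day 4 control and 0.187 and 1.73 CPM in day 4 cKO. Summed erythrocyte markers in background droplets were 144 CPM in sham, 106 and 1924 CPM in day 4 control and 49.1 and 47.4 CPM in day 4 cKO, so free erythroid RNA was lower in both cKO libraries too. In day 4 control replicate 1, however, free erythroid RNA was lower than in sham, while Hbb-bs in oligodendrocyte-like cells was higher than in sham. Hbb-bs has a near-identical copy, Hbb-bt, so its counts are uncertain. Leaving out control replicate 1, control replicate 2, cKO replicate 1 or cKO replicate 2 gave 3, 27, 0 and 17 genes. Of the 20 gene lists 9 passed camera for the knockout in these cells, and with an estimated correlation none did (adjusted p = 0.61 to 0.95). The lowest camera p belonged to endoplasmic reticulum stress (18 of 24 lower, median log2 fold change -0.60, camera adjusted p = 1.1e-05, adjusted p = 0.61 with an estimated correlation), with 4 members that fell when adjusted over the list alone. Of 24 axon injury genes 18 were higher (camera adjusted p = 2.4e-04, adjusted p = 0.69 with an estimated correlation) and 1 rose when adjusted over the list alone. Of 18 heat shock genes 17 were lower (camera adjusted p = 2.7e-04, adjusted p = 0.75 with an estimated correlation), and 4 fell and 1 rose when adjusted over the list alone. Interferon-response genes, not called in neurons, passed camera as lower here, with 7 of 23 higher (median -0.44, camera adjusted p = 0.019, adjusted p = 0.75 with an estimated correlation). The mix of oligodendrocyte-like clusters differed between the genotypes and was not separated from a change inside clusters. The cluster led by Gdf15 and Tnfrsf12a held 281 and 9 day 4 control cells and 44 and 4 day 4 cKO cells. The cluster led by Trf and Klk6 held 148 and 16 against 447 and 7. A cluster of oligodendrocyte precursor-like cells led by the cell division genes Cenpf, Top2a and Mki67 held 2 sham cells, 80 and 0 day 4 control cells and 31 and 0 day 4 cKO cells.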
